A study of Mus musculus with 6 samples.

How the data were processed

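RNA sequencing libraries came from neural stem cells that had been isolated from the subgranular zone of the mouse hippocampus, the layer of the dentate gyrus where neurons are generated in adult life, and grown to passage 3. Of the 6 libraries, 3 came from cultures exposed to 0.8 μM cadmium chloride for 72 h and 3 from untreated cultures of the same time. Groups and replicate numbers were taken from the labels. The labels call the replicates biological but do not say whether they came from separate animals or separate platings, so the p-values measure the spread between these samples, part of which can be technical. Per the labels' protocols, total RNA was enriched for mRNA, fragmented and reverse transcribed before sequencing on an Illumina platform. A strand setting is not given in the sources used here.

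The deposited table of counts holds whole numbers of reads per gene, made by the authors. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.0, HTSeq 0.11.2, DESeq2 1.22.2 and the mouse genome build GRCm39, without saying which step each served. The gene annotation used by the authors is not given in the sources used here. The deposited FPKM values (reads scaled by gene length and library total) were recomputed from the counts as a check. Each equalled the count divided by the library total and by 1 whole-number length per gene, with a largest relative deviation of 1.63e-08, so both tables hold the same measurement. Neither table holds rows that name no gene. Gene symbols and Entrez identifiers are those of the deposited tables. Reads from an antisense or overlapping gene cannot be told apart where counting ignores strand, and genes with near-identical copies, such as ribosomal protein genes, histone genes, Gapdh and the pair Hspa1a and Hspa1b, can share or lose reads.

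Library totals lay between 37710042 and 41523231 counts. Replicates of a group were compared by a chi-square statistic over genes, which was 3.43 to 12.8 per degree of freedom for the 6 pairs within groups, so no library repeated another within sampling noise. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM scaling, group as the only term). The filterByExpr rule with a minimum count of 10 and a minimum total of 15 left 14369 of 25241 genes, which held 99.96% of all counts. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested. A gene is said to have changed at an adjusted p below 0.05. Log2 fold changes are cadmium over control, and their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are in CPM, counts scaled to a common library total, given as mean ± SD of 3 libraries.

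The 41 gene lists were fixed before the data were examined, as were the main tests, the naming rule and all alternatives except 1. Tests chosen after the data were seen are said to be so where they appear. The lists cover metal handling, stress responses, the cell cycle, stem cell and lineage identity, signalling, metabolism, other cell types a primary culture can hold, and signs of RNA quality. Lists with at least 5 genes tested (38 of 41) entered camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over these lists. The test was repeated with the correlation estimated for each list and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Counts of members that rose and fell were also made with p-values adjusted over the list alone. Pathway and ontology terms paired with genes in the deposited tables, with 10 to 500 members among the genes tested that carry a term of that kind, were tested by a one-sided hypergeometric test, separately for genes that rose and that fell. This test takes genes as independent draws, so its p-values do not measure the spread between cultures.

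Named genes follow a fixed rule. Mt1, Mt2, Mt3, Hmox1, Slc30a1, Nes, Sox2, Mki67, Dcx and Gfap are given whatever their result. The 12 largest rises and the 12 largest falls are taken from genes that passed the threshold, had a mean of at least 5 CPM in a group and had all cadmium libraries on one side of all control libraries, leaving out predicted genes, clone names and pseudogenes. From each list, up to 4 members are taken, those with the smallest p among members that rose and among members that fell, or the most highly expressed where none passed. Some genes that this rule selects are not reported here, though they count in totals and gene lists. Other genes are said to be chosen after their values were seen.

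The edgeR fit was tested on simulated counts for this comparison, with 50 genes at each fold size among 14234 genes. It recovered 62% of genes with a simulated change of 1.25-fold, 82% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. Of all its calls, 6.15% were false. The changed genes had a mean of at least 1 CPM, and genes were simulated independently. In the data 45.5% of the genes tested changed, far more than in the simulation, so these shares need not hold there. Alternatives were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, a replicate block, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1 with and without an FPKM minimum of 0.5, and leaving out each library in turn. A correction for gene length and GC content was added after the data were seen. Length was the length per gene implied by the deposited counts and FPKM values. GC content was taken from a mouse annotation of another build and matched by name, so no coordinates are given. Both were available for 94.1% of the genes tested.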

Results

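Transcript levels were measured by RNA sequencing in 3 untreated and 3 cadmium-treated cultures of mouse subgranular zone neural stem cells, to find which genes respond to 0.8 μM cadmium chloride after 72 h. Total counts were 40634758, 41523231 and 41511149 in control replicates 1, 2 and 3, and 40678437, 37710042 and 40748613 in cadmium replicates 1, 2 and 3. The group means were 41223046 ± 509508 and 39712364 ± 1734420 counts (SD, n = 3), a difference within the spread between replicates (exact permutation test, two-sided, p = 0.3, where 3 against 3 allows no p below 0.1). Mitochondrial transcripts took 3.35 ± 0.138% of counts in control and 3.29 ± 0.204% in cadmium libraries (exact permutation p = 0.6, n = 3). Ribosomal protein transcripts took 3.86 ± 0.0910% and 4.21 ± 0.123%, which is complete separation and the smallest p the design allows (exact permutation p = 0.1, n = 3). Genes with a count numbered 18952 ± 69.3 in control and 19299 ± 233 in cadmium libraries, which were also completely separated (exact permutation p = 0.1, n = 3).

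Cadmium and control libraries separated along the first principal component, which held 65.0% of the variance. Control replicate 3 had a score of -36.9 on it, further from the cadmium libraries than control replicates 1 and 2 at -23.4 and -22.4, and the cadmium libraries scored 24.0, 32.0 and 26.8. Pearson correlations across genes, which are not independent replicates, were 0.993 to 0.995 within groups and 0.977 to 0.986 between them.

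**Figure D1:**
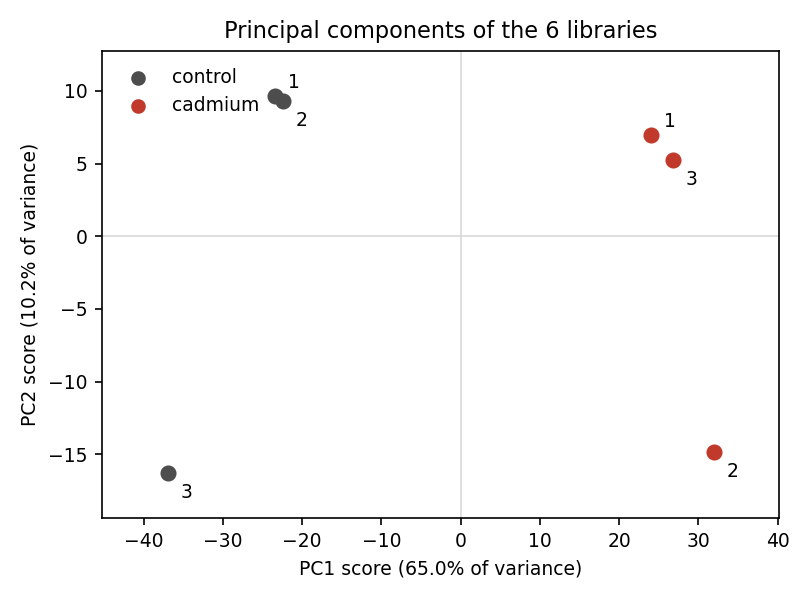
Scores of the 6 libraries on the first and second principal components of log2 CPM (log2 of scaled counts) of the genes tested, with the share of variance on each axis, control in grey, cadmium in red and the replicate number beside each point. The control libraries lie between -36.9 and -22.4 on the first component and the cadmium libraries between 24.0 and 32.0.

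Cadmium exposure was followed by higher transcript levels of Mt1, Mt2, Hmox1 and Slc30a1. Metallothionein genes Mt1 (Entrez 17748) and Mt2 (17750), whose products bind cadmium and zinc, rose from 562 ± 59.3 to 1278 ± 18.3 CPM and from 226 ± 33.6 to 736 ± 31.7 CPM (SD, n = 3). Their log2 fold changes were 1.19 ± 0.06 (SE, edgeR adjusted p = 1.4e-07) and 1.71 ± 0.11 (adjusted p = 2.2e-05). Heme oxygenase gene Hmox1 (15368) rose from 93.5 ± 5.80 to 348 ± 7.42 CPM, a log2 fold change of 1.90 ± 0.05 (adjusted p = 2.4e-12). The zinc exporter gene Slc30a1 (22782) rose from 32.5 ± 1.58 to 68.2 ± 2.07 CPM, 1.07 ± 0.05 (adjusted p = 1.4e-08). Mt3, the metallothionein of the nervous system, was at 253 ± 18.3 and 245 ± 3.52 CPM (log2 fold change -0.05 ± 0.05, adjusted p = 0.45).

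Among the markers of cell state, Nes, which encodes the stem cell intermediate filament nestin, rose from 363 ± 26.2 to 623 ± 33.6 CPM (0.78 ± 0.05). Gfap, the intermediate filament gene of astrocytes and radial stem cells, fell from 2809 ± 466 to 875 ± 64.2 CPM (-1.68 ± 0.13, SE, n = 3). The transcription factor gene Sox2 fell by less (602 ± 27.0 to 499 ± 20.0 CPM, -0.27 ± 0.04). Dcx, a marker of young neurons, was low and fell from 4.07 ± 0.448 to 2.12 ± 0.411 CPM (-0.94 ± 0.17). The proliferation marker Mki67 was at 489 ± 41.4 and 501 ± 7.54 CPM (0.03 ± 0.05, edgeR adjusted p = 0.61).

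**Figure D2:**
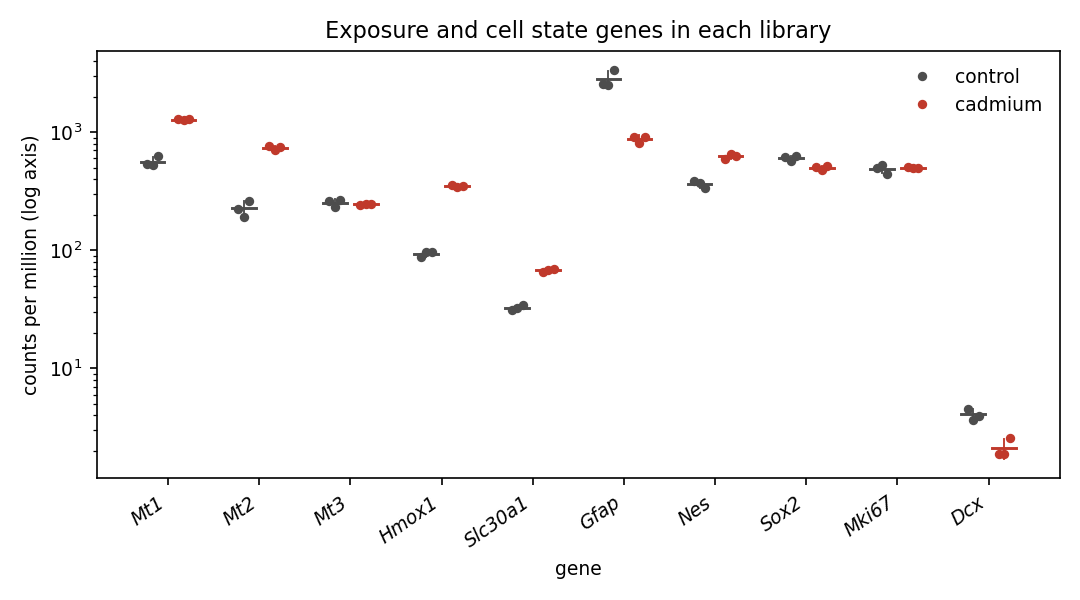
CPM, on a log axis, of 10 genes named before the data were examined, with a point per library, a horizontal line at the mean and a vertical line for the SD of 3 libraries, control in grey and cadmium in red. Hmox1 rose from a mean of 93.5 to 348 CPM and Gfap fell from 2809 to 875 CPM, while Mt3 and Mki67 overlap between groups.

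Across all genes tested, 3313 rose and 3221 fell, together 6534 or 45.5% of 14369. Most of these changes were small, with 4931 (75.5%) below 1.5-fold. At least 2-fold, 285 genes rose and 351 fell. These numbers were 67 and 114 with at least 5 CPM in 3 libraries, 88 and 141 on log2(FPKM + 0.1) and 29 and 58 on log2(FPKM + 1), with or without an FPKM minimum. In 56.3% of the genes tested all 3 cadmium libraries lay on one side of all 3 control libraries, against 10% by chance. Of the changed genes, 6382 were separated in this way. Among genes with a mean of at least 5 CPM in a group and separated in this way, leaving out predicted genes, clone names and pseudogenes, the largest rise was that of Osgin1, an oxidative stress response gene, from 0.313 ± 0.170 to 6.72 ± 0.598 CPM (4.40 ± 0.24). It was followed by Epha2 (2.28), Tmem179 (2.09), Itga8 (2.04), Apln (1.90), Hmox1 (1.90), F2rl1 (1.83), Cd93 (1.72), Mt2 (1.71), Gdf15 (1.70), Esrrb (1.68) and Hmga2 (1.66). By the same rule, the largest fall was that of Entpd2, an ectonucleotidase gene, from 5.10 ± 1.58 to 0.722 ± 0.0756 CPM (-2.81 ± 0.24). Gpr17 (-2.33), Naaa (-2.33), Padi2 (-2.26), Dkk3 (-1.97), the zinc and manganese transporter gene Slc30a10 (-1.97), Niban1 (-1.96), Siah3 (-1.81), Tmem100 (-1.79), Retreg1 (-1.77) and Lims2 (-1.73) were among those that came next.

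The antioxidant genes driven by the transcription factor NRF2 rose as a group. Of 26 tested, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 3.5e-08). This became adjusted p = 0.32 with an estimated correlation. Besides Hmox1, Srxn1, which encodes sulfiredoxin, rose from 25.2 ± 0.994 to 75.4 ± 3.58 CPM (1.58 ± 0.06). Ugdh fell (-0.38 ± 0.05). Genes of the integrated stress response rose in 19 of 23 cases and fell in 1 (20 and 1 adjusted over the list alone). Their median was 0.48 (adjusted p = 7.2e-07; adjusted p = 0.32 with an estimated correlation). The cystine transporter gene Slc7a11 rose from 7.91 ± 0.883 to 23.6 ± 2.36 CPM (1.57 ± 0.10) and the amino acid transporter gene Slc7a5 by 0.48 ± 0.04. Ddit4, an mTOR inhibitor gene, fell (-0.68 ± 0.09).

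Chaperone and p53 target genes also moved upward. Of 19 heat shock genes, mostly of cytosolic chaperones, 14 rose and 3 fell, both over all genes and adjusted over the list alone. The median was 0.25 (camera adjusted p = 0.0018; adjusted p = 0.49 with an estimated correlation). The mitochondrial chaperonin gene Hspd1 (0.44 ± 0.05) and Hspa4 (0.38 ± 0.05) were among those that rose, and Dnajb4 (-0.24 ± 0.06) and Cryab (-0.25 ± 0.07) fell. The Cryab call was lost without cadmium replicate 2 (adjusted p = 0.052) and on log2(FPKM + 1) with no FPKM minimum (0.071; range over its alternatives 0.00040 to 0.071), where 1 heat shock gene fell. Of 18 endoplasmic reticulum chaperone genes, 9 rose and 0 fell, adjusted over the list alone too. Their median was 0.16 (adjusted p = 0.0089; adjusted p = 0.49 with an estimated correlation), with Hyou1 at 0.39 ± 0.05 and Dnajb11 at 0.30 ± 0.05. Of 21 p53 targets, 13 rose and 3 fell (13 and 4 adjusted over the list alone). The median was 0.26 (adjusted p = 0.038; adjusted p = 0.42 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 0.46 ± 0.05 and Pmaip1 by 0.73 ± 0.09. Both Sesn1 (-0.58 ± 0.05) and Btg2 (-0.74 ± 0.07) fell. The p53 call was lost without cadmium replicate 3 (adjusted p = 0.053) and under the length and GC correction (0.058; range over its alternatives with a preset correlation or fry 0.0035 to 0.058).

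DNA replication genes rose almost without exception. Of 29 tested, 28 rose and 0 fell (29 and 0 adjusted over the list alone). The median was 0.50 (camera adjusted p = 2.9e-10; adjusted p = 0.49 with an estimated correlation). Cdc6, which loads the replicative helicase, rose from 15.3 ± 2.19 to 30.9 ± 1.499 CPM (1.01 ± 0.09) and the helicase gene Mcm7 from 194 ± 10.1 to 259 ± 11.8 CPM (0.42 ± 0.05). Genes of double-strand break and fork repair rose in 17 of 21 cases (18 adjusted over the list alone) and fell in 0 (median 0.35, adjusted p = 1.2e-05; adjusted p = 0.49 with an estimated correlation). Chek1 (0.73 ± 0.10) and Rad51ap1 (0.49 ± 0.07) were among them. On log2(FPKM + 1) with no FPKM minimum 9 of these repair genes rose. Of 30 mitosis genes, 13 rose and 3 fell, adjusted over the list alone too, with a median of 0.09 (adjusted p = 0.048; adjusted p = 0.49 with an estimated correlation). Aurkb (0.25 ± 0.05) and Cdk1 (0.19 ± 0.04) rose, and Ccnb2 (-0.18 ± 0.05) and Nusap1 (-0.17 ± 0.04) fell. Broader annotated terms were enriched among all genes that rose. The Reactome term Cell Cycle, Mitotic had 218 of 449 members against 125.8 expected (hypergeometric adjusted p = 4.9e-19). M Phase had 151 of 334 against 93.6 (adjusted p = 5.8e-10), and Mitotic Metaphase and Anaphase 99 of 211 against 59.1 (adjusted p = 1.9e-07). S Phase (75 of 140 against 39.2) and G1/S Transition (58 of 102 against 28.6) were enriched too. Genes shared between terms were not removed, so these counts are not evidence on mitosis alone. The replication median exceeded the mitosis median by 0.41. In a test chosen after the data were seen, the median of the replication genes minus that of the mitosis genes was taken in each library, on log2 CPM minus each gene's mean. It was -0.22 ± 0.10 in control and 0.22 ± 0.05 in cadmium libraries (SD, n = 3, two-sided exact permutation p = 0.1, the smallest the design allows), and -0.34 in control replicate 3. The mitosis call was lost in 9 of 15 alternatives with a preset correlation or fry. It was lost on leaving out control replicate 1 (adjusted p = 0.054), control replicate 3 (0.14), cadmium replicate 1 (0.063), cadmium replicate 2 (0.070) or cadmium replicate 3 (0.057; range over its alternatives with a preset correlation or fry 0.023 to 0.14). The number of mitosis genes that rose was 5 without cadmium replicate 2, without cadmium replicate 3 or on log2(FPKM + 1) with no FPKM minimum, and their median was 0.05 without control replicate 3. Control replicate 3 differed from control replicates 1 and 2 in the same lists, with medians of -0.26 for replication and -0.08 for mitosis genes.

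Ribosomal protein genes rose by small amounts. Of 79, 55 rose and 0 fell (59 and 0 adjusted over the list alone). The median was 0.15 (camera adjusted p = 3.5e-08; adjusted p = 0.49 with an estimated correlation). The median was 0.15 under median-of-ratios and 0.14 under upper-quartile scaling. Without cadmium replicate 2 or cadmium replicate 3 the number that rose was 31 and 35, and on log2(FPKM + 1) with no FPKM minimum 26. Reads of these genes can be shared with pseudogenes, which was not tested. Among annotated terms, 479 of 4991 were enriched among genes that rose, led by ribosome production. The hypergeometric test of terms makes no allowance for correlation between genes, and its p-values do not measure the spread between cultures. For the replication list the correlation estimated by camera was 0.80. The Reactome term rRNA processing had 125 of 169 members rising against 47.3 expected (adjusted p = 6.6e-33). The KEGG term Ribosome biogenesis in eukaryotes had 60 of 73 against 20.8 (adjusted p = 6.4e-19), and the ontology term DNA replication 69 of 112 against 26.7 (adjusted p = 6.5e-15). Among genes that rose at least 2-fold 22 terms were enriched, 0 of them among the 479. The calls of all these terms, those of the cell cycle included, were therefore lost there. The replication list had a median of 0.50 and a highest log2 fold change of 1.01, so few of its genes could enter that set. This cut thus cannot test terms made of small changes.

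Astrocyte markers fell together. Of 18 tested, 17 fell and 0 rose, adjusted over the list alone too. The median was -0.72 (camera adjusted p = 3.5e-08; adjusted p = 0.49 with an estimated correlation). Sparcl1, a matrix protein gene of astrocytes, fell from 272 ± 15.6 to 170 ± 3.17 CPM (-0.68 ± 0.05). Oligodendrocyte lineage markers fell in 8 and rose in 3 of 15 cases (9 and 3 adjusted over the list alone). The number that rose was 0 without control replicate 1, without cadmium replicate 2 or on log2(FPKM + 1) with no FPKM minimum, and 1 without cadmium replicate 3. The median of the 15 markers was -0.47 (adjusted p = 0.0080; adjusted p = 0.49 with an estimated correlation), -0.31 without control replicate 3 and -0.23 on log2(FPKM + 1) with no FPKM minimum. Pdgfra, the receptor gene of oligodendrocyte precursors, fell from 104 ± 6.47 to 52.5 ± 2.58 CPM (-0.98 ± 0.06) and Sox10 by 1.05 ± 0.10 on the log2 scale. Olig1 (0.11 ± 0.04) and Nkx2-2 (0.23 ± 0.07) rose slightly, both calls being lost without cadmium replicate 2 (adjusted p of 0.10 and 0.11) and without some other libraries (ranges over their alternatives 0.0053 to 0.12 and 0.0029 to 0.11). Reactive astrocyte markers fell in 8 and rose in 3 of 17 cases (9 and 3 adjusted over the list alone). The median was -0.56 (adjusted p = 0.016; adjusted p = 0.33 with an estimated correlation), with Serpina3n at -1.27 ± 0.07 and Emp1 at -1.18 ± 0.11. Vim (0.22 ± 0.04) and Cd44 (0.27 ± 0.04) rose. The reactive astrocyte call was lost with at least 5 CPM in 3 libraries, where 10 genes were tested and the median was -0.34 (adjusted p = 0.065; range over its alternatives with a preset correlation or fry 0.0022 to 0.065). On log2(FPKM + 1), with or without an FPKM minimum, the median was -0.28. In control replicate 3 the astrocyte median was 0.18 and the oligodendrocyte median 0.20 above control replicates 1 and 2.

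Genes of the Notch pathway, which maintains stem cells, fell in 13 and rose in 2 of 19 cases (13 and 3 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.00045; adjusted p = 0.32 with an estimated correlation). The feedback inhibitor gene Nrarp fell from 72.5 ± 5.37 to 43.4 ± 1.73 CPM (-0.74 ± 0.06) and the ligand gene Dll3 from 71.5 ± 9.54 to 36.6 ± 1.97 CPM (-0.97 ± 0.08). Jag1 (0.80 ± 0.19) and Lfng (0.22 ± 0.05) rose. Stem cell markers went both ways, with 7 rising and 9 falling of 22 (7 and 10 adjusted over the list alone; median -0.10, adjusted p = 0.31). Id4, an inhibitor of differentiation factors, fell from 40.4 ± 5.49 to 12.7 ± 1.15 CPM (-1.67 ± 0.10), and Sox9 fell by 0.39 ± 0.04 on the log2 scale.

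Fatty acid oxidation genes fell in 15 and rose in 0 of 18 cases, adjusted over the list alone too. The median was -0.28 (camera adjusted p = 1.2e-05; adjusted p = 0.49 with an estimated correlation), with Decr1 at -0.51 ± 0.06 and Etfdh at -0.44 ± 0.05. Lysosome and autophagy genes fell in 17 and rose in 2 of 27 cases (19 and 2 adjusted over the list alone). Their median was -0.20 (adjusted p = 0.0025; adjusted p = 0.49 with an estimated correlation) and -0.13 without control replicate 3, with Hexa at -0.35 ± 0.04 and Lamp2 at -0.34 ± 0.04. The autophagy receptor gene Sqstm1 rose (0.38 ± 0.05). Lipid synthesis genes fell in 9 and rose in 1 of 17 cases (9 and 2 adjusted over the list alone). Here the median was -0.18 (adjusted p = 0.015; adjusted p = 0.33 with an estimated correlation), with Gpam at -0.82 ± 0.07 and Acss2 at -0.50 ± 0.04. In the hypergeometric test, which takes genes as independent, 61 of 4991 terms were enriched among genes that fell. They included the ontology term lysosome (154 of 364 members against 83.5 expected, adjusted p = 3.7e-13), Fatty acid metabolism (66 of 120 against 26.8, adjusted p = 1.2e-11) and Valine, leucine and isoleucine degradation (31 of 47 against 10.6, adjusted p = 2.8e-07). Among genes that fell at least 2-fold 12 terms were enriched, 1 of them among the 61, and the calls of these 3 terms were lost. The largest fall in the lysosome and autophagy list was -0.42, so the genes of that list could not enter this set. In control replicate 3 the fatty acid oxidation median was 0.09 and the lysosome median 0.11 above control replicates 1 and 2.

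Glycolysis and hypoxia genes rose in 11 and fell in 4 of 26 cases, adjusted over the list alone too (median 0.15, camera adjusted p = 0.039; adjusted p = 0.49 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 29.3 ± 1.66 to 52.2 ± 0.552 CPM (0.83 ± 0.06) and Pfkp by 0.65 ± 0.06. Both Slc2a3 (-0.64 ± 0.06) and Pfkm (-0.34 ± 0.04) fell. This call was lost without control replicate 1, cadmium replicate 2 or cadmium replicate 3 (adjusted p of 0.094, 0.076 and 0.053; range over its alternatives with a preset correlation or fry 0.010 to 0.094). Interferon-stimulated genes fell in 6 and rose in 0 of 19 cases, adjusted over the list alone too. Their median was -0.28 (adjusted p = 0.015; adjusted p = 0.49 with an estimated correlation), with Stat2 at -0.42 ± 0.06. The call was lost without control replicate 3 (adjusted p = 0.058; range over its alternatives with a preset correlation or fry 0.0036 to 0.058), and on log2(FPKM + 1) with no FPKM minimum the median was -0.11.

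**Figure D3:**
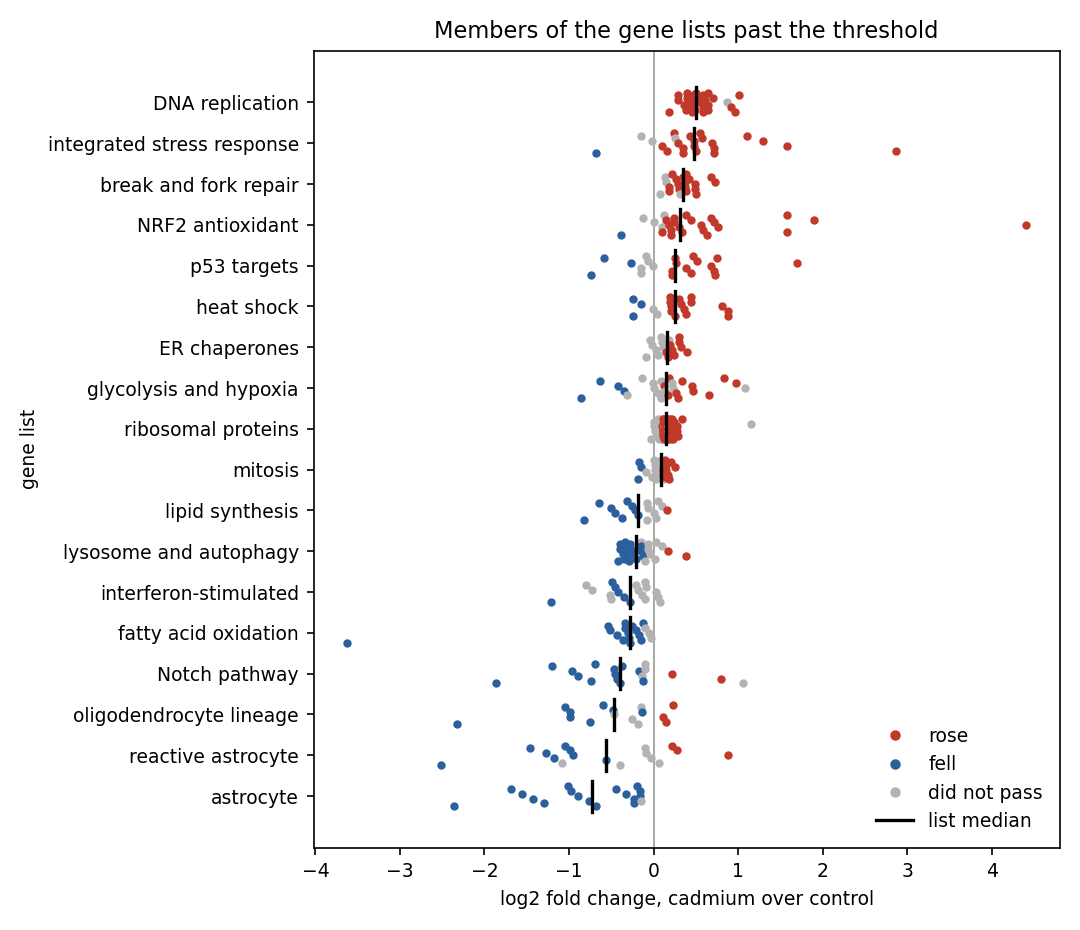
Log2 fold change of cadmium over control for each member (points) of the 18 gene lists that passed the threshold with a preset correlation, with members that rose in red, that fell in blue and that did not pass in grey, and a black bar at each list's median. The medians run from -0.72 for astrocyte markers to 0.50 for DNA replication genes.

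In all, 18 of 38 lists passed with the preset correlation, 10 upward and 8 downward. With a correlation estimated for each list 0 passed in camera (5 at an unadjusted p under 0.05), the lowest adjusted p being 0.32. That version of the test rests on the 4 residual degrees of freedom of the design. The estimated correlation was 0.80 for replication genes. For p53 targets it was 0.0052, below the preset 0.01, yet their unadjusted camera p went from 0.016 to 0.066. Loss of a call there is therefore not by itself a sign of correlation between genes. The fry test called 26, among them lists that did not pass in camera. Of these, neuroblast, metal handling, ferroptosis, calcium channel and reference genes were called upward. Stem cell, activated progenitor, BMP and quiescence, and inflammation genes were called downward. The remaining 20 lists did not pass with the preset correlation. Metal handling genes rose in 8 and fell in 2 of 20 cases (median 0.05, camera adjusted p = 0.12). BMP and quiescence genes rose in 4 and fell in 11 of 20 (median -0.19, adjusted p = 0.11) and immediate early genes rose in 7 and fell in 1 of 20 (median 0.21, adjusted p = 0.062). The immediate early list passed in 6 of 15 alternatives with a preset correlation or fry (range 0.0027 to 0.18), among them without control replicate 2 (adjusted p = 0.0027, 11 rising, median 0.41) and without cadmium replicate 1 (0.030), while 4 rose without control replicate 1. The BMP and quiescence list passed in 5 of 15 (range 0.0092 to 0.14), and 2 of its genes rose without cadmium replicate 2 or cadmium replicate 3. Replication-dependent histone genes fell in 4 and rose in 0 of 19 cases (median -0.24, adjusted p = 0.10). That list passed in 3 of 14 alternatives, among them without control replicate 2 (adjusted p = 0.041, range 0.041 to 0.56), its median was -0.10 without control replicate 3, and mRNA selection and shared reads limit what their counts show. Core apoptosis genes rose in 8 and fell in 5 of 22 cases and ferroptosis genes in 8 and 2 of 19. Activated progenitor genes rose in 2 and fell in 7 of 13, Wnt genes in 7 and 8 of 23, neuroblast markers in 5 and 3 of 15 and mature neuron markers in 3 and 2 of 18. Respiratory chain genes of the nucleus rose in 6 and fell in 12 of 77 cases, mitochondrially encoded genes in 2 and 0 of 13 and cholesterol synthesis genes in 5 and 4 of 25. Nuclear respiratory chain genes fell in 4 cases without cadmium replicate 1 and in 7 without cadmium replicate 3, and rose in 2 without cadmium replicate 2 and in 3 without cadmium replicate 3. Of the mitochondrially encoded genes, 4 rose without cadmium replicate 2 and 3 fell without control replicate 1. Core apoptosis genes fell in 3 cases without control replicate 2 or cadmium replicate 2, Wnt genes rose in 4 without cadmium replicate 1 and cholesterol synthesis genes in 3 without cadmium replicate 2. For cholesterol synthesis the median was -0.02 while the direction of camera was upward (adjusted p = 0.98). The same counts were, for inflammation genes, 1 and 5 of 12, for matrix and adhesion genes 12 and 8 of 27 and for calcium channel genes 6 and 1 of 21. Fibroblast markers rose in 0 and fell in 3 of 10 cases, RNA quality transcripts in 1 and 1 of 7 and reference genes in 5 and 3 of 15. Without cadmium replicate 3, 1 fibroblast marker fell, as without cadmium replicate 1, and of the reference genes 3 rose and 1 fell (3 rose without control replicate 2). Adjusted over the list alone, the counts of these lists differed by at most 2 genes in a direction, except for nuclear respiratory chain genes (4 and 7). Of microglia, vascular and ependymal markers, 2, 4 and 4 genes were expressed enough to be tested, of which 1, 0 and 1 rose and 0, 2 and 2 fell.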

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

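The number of genes changed was within 1.5 times the 6534 reported under the alternatives chosen beforehand (5342 to 6853) and under a correction for length and GC content chosen after the data were seen (6721). Calls shared with the reported ones had the same direction in each. Leaving out 1 library at a time gave 5370 to 6162 genes, 571 to 709 at 2-fold and 15 to 20 lists. The count at 2-fold fell from 636 to 181 with at least 5 CPM in 3 libraries, and to 87 on log2(FPKM + 1), 229 on log2(FPKM + 0.1) and 87 on log2(FPKM + 1) with no FPKM minimum, where model and scale change together. Requiring a 2-fold change left 22 terms among genes that rose (0 of the 479) and 12 among genes that fell (1 of the 61), from smaller gene sets. Terms whose genes changed by small amounts could not pass that cut, so their loss there does not test them. With an estimated correlation 0 of 38 lists passed. In counts simulated with independent genes at this size a list of 27 genes raised by 0.3 on the log2 scale passed (camera adjusted p = 0.013). In the data that list, of lysosome and autophagy genes, had an estimated correlation of 0.46. The simulation therefore does not show whether such a change could be found here. There were 2508 alternatives of 149 genes selected by the naming rule. Of these, 2458 left the gene called or uncalled as before, 50 lost the call (16 genes) and 0 reversed a call. Most of these genes were selected by p-value or fold change in the same data, which favours keeping the call. Over all genes, 5219 of the 6534 calls were kept without cadmium replicate 3. On log2(FPKM + 1) with no FPKM minimum 4924 were kept. Of 603 alternatives of lists, 547 left the list called or uncalled as before, 34 lost the call, 22 gained it and 0 reversed a call. Uncalled genes changed direction in 1 alternative and uncalled lists in 6. With the replicate number as a block, 6509 genes changed. Deviations of same-numbered libraries correlated at 0.0234, 0.0517 and -0.0105, and those of differently numbered libraries at -0.0488 to 0.0284. With 3 libraries in a group these values cannot tell whether the numbers mark a pairing. The first component held 65.0% of the variance, and 73.5% over the 500 most variable genes.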

Other observations

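The groups and genes in this and the following paragraph were chosen after their values were seen, from 18 groups looked at. The tests of a state shared with untreated cultures for the astrocyte markers, of astrocyte-like cells, of the shift per marker or gene and of MAPK output were also chosen after seeing the result. Of 16 genes of nucleolar ribosome production and of the Myc family and its targets, 14 rose and 2 fell (median 0.50; camera adjusted p over the 18 groups 0.00017, adjusted p = 0.39 with an estimated correlation). The median of these genes in control replicate 3 was -0.20 against control replicates 1 and 2, opposite to cadmium, and without that library 13 rose and 2 fell. Nop56 rose from 55.3 ± 6.79 to 92.2 ± 4.19 CPM (0.74 ± 0.08) and Rrp9 from 17.3 ± 2.85 to 30.2 ± 3.18 CPM (0.80 ± 0.11), and Myc rose (0.46 ± 0.12) while Mycn fell (-1.19 ± 0.14). Of 471 C2H2 zinc finger transcription factor genes, 122 fell and 27 rose (median -0.13, camera adjusted p = 0.0023, adjusted p = 0.39 with an estimated correlation), and without control replicate 3 the numbers were 128 and 25. Over all 14369 genes tested 3221 fell and 3313 rose, so these genes differed mainly in how few rose.

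Single genes stood out as well. The NRF2 target Nqo1 was at 17.9 ± 2.32 and 16.4 ± 0.599 CPM (-0.13 ± 0.09, edgeR adjusted p = 0.26), while Gclm (0.58 ± 0.05), Gclc (0.45 ± 0.05) and Txnrd1 (0.63 ± 0.04) rose. Imprinted genes went both ways (5 rose and 4 fell of 17, median -0.04, camera direction upward with an adjusted p of 0.70). Peg10 rose from 34.8 ± 5.12 to 90.8 ± 0.921 CPM (1.38 ± 0.08) and Mest from 318 ± 43.6 to 654 ± 11.9 CPM (1.04 ± 0.09), and H19 fell from 19.8 ± 3.76 to 8.74 ± 0.305 CPM (-1.18 ± 0.12).

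The split of the 6 libraries by treatment gave 6534 changed genes, and the highest edgeR count among the other 9 of the 10 splits was 0 (at most 299 genes at an unadjusted p under 0.05), so 1 split gave as many. With 10 splits a share under 0.05 cannot be reached.

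For the fall of astrocyte markers, a trend with gene length and GC content was tested first. After its removal the median of the 18 markers was -0.72, against -0.72 before, with a bootstrap interval over markers (-1.13 to -0.23) too wide for the bound set beforehand, but the shift per marker was 0.02 (0.01 to 0.03), which argues against that trend. A state that also varies between untreated cultures remains a candidate explanation for part of the fall, since across genes, which are not independent, control replicate 3 minus control replicate 1 correlated with cadmium minus control replicate 2 at r = -0.245 (-0.27 with control replicates 1 and 2 exchanged, -0.03 for control replicate 1 minus 2 against cadmium minus 3). The markers were 0.18 higher in control replicate 3 than in control replicates 1 and 2, and the cadmium change against these was -0.65. Other lists differed less in control replicate 3, with medians of 0.02 for NRF2, -0.004 for integrated stress response and 0.05 for Notch genes. The cadmium medians of these 3 lists against control replicates 1 and 2 were 0.31, 0.46 and -0.35. A smaller share of astrocyte-like cells cannot be told apart from lower expression per cell in bulk libraries. A smaller share alone would lower the markers by about the same factor. Their log2 fold changes had an interquartile range of 0.99 with 17 of 18 falling, which is not such a uniform fall. Markers also expressed by other cells would fall less, so this leaves the question open.

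The excess of replication over mitosis genes was 0.39 after removal of the length and GC trend, against 0.41 before. The shift per gene was 0.02 for replication and 0.01 for mitosis genes, which argues against that trend. Bootstrap intervals over genes (here 0.34 to 0.55) take genes as independent and do not measure the spread between cultures. Growth state may account for the excess in part, since control replicate 3 differed from control replicates 1 and 2 the opposite way. The medians there were -0.26 for replication and -0.08 for mitosis genes (size of the mitosis minus the replication median -0.176, bootstrap interval over genes -0.25 to -0.12). This rests on a single library. The cadmium libraries differed from control replicates 1 and 2 by 0.42 for replication and 0.06 for mitosis genes. Control replicate 3 thus moved less than cadmium in replication genes and further in mitosis genes, which is a different proportion. Whether cadmium sets such a growth state or the cultures differed in density stays open.

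The rise of ribosomal protein genes had a median of 0.16 after removal of the length and GC trend (bootstrap interval over genes 0.13 to 0.17), against 0.15 before. The shift per gene was 0.01, which argues against that trend as the cause. These intervals, too, take genes as independent. Under upper-quartile scaling, the lower of both other scalings, it was 0.14 (interval 0.12 to 0.16). The median log2 fold change of all genes was -0.010 under TMM, -0.006 under median-of-ratios and -0.019 under upper-quartile scaling. These scalings differed too little to move the ribosomal median far, so their agreement cannot decide whether scaling caused the rise. Ribosomal protein genes were 0.08 higher in control replicate 3 than in control replicates 1 and 2, so here the untreated library that stands apart moved the same way as cadmium. Reads shared with pseudogenes were not tested.

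Higher MAPK/ERK output may be part of the response, a hypothesis prompted by Epha2, Ccnd1 and Dusp4. Of the other 7 members of a 10-gene list of MAPK output recalled from general knowledge, 4 rose and 1 fell (Spry4 0.98 ± 0.25, Etv5 0.76 ± 0.08 and Etv4 0.48 ± 0.08 among those that rose, Epha4 -0.70 ± 0.07). Their camera p was 0.049, but all members' values had been seen and 18 groups looked at. Multiplied by that number it was 0.88 (p = 0.30 before multiplication with an estimated correlation), so the test leaves it open. These 7 genes were also lower in control replicate 3 (median -0.27), and without that library 3 rose and 1 fell.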
